A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

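Ribosome footprints and mRNA of Saccharomyces cerevisiae strain 74D694 were measured in 10 samples. Per the labels, cells grew at 30 °C to an OD600 of 0.6 to 0.8 and were treated with cycloheximide, which stalls elongating ribosomes. The rich medium (YPD) experiment compared [PSI+] with [psi-] cells in 4 footprint and 2 mRNA libraries. The synthetic medium (YNB with 2% glucose, without uracil) experiment compared [PSI+] cells with and without overexpressed SUP35-Cter in 4 footprint libraries. Groups came from the sample titles.

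For the YPD experiment, reads were counted per gene with HTSeq 0.5.3p3 in intersection-nonempty mode by the authors, per the deposited description, after mapping that the submitters' processing notes tie to Bowtie 0.12.7 and the build sacCer2. The deposited counts are whole numbers over 6608 features with no value below 1, which shows that 1 had been added to each; this was subtracted as an alternative, and read numbers in the text are without it. How reads that map to several places were treated, and whether counting used the strand, is not given in the sources used here. The library kit was directional per the labels. Near-identical gene copies, overlapping genes and antisense genes are therefore uncertain. The authors' table for this experiment was made with DESeq 1.6.1, per the submitters' processing notes. It holds a base mean signal per condition (counts divided by size factors by the authors), a linear fold (ratio of both means) and a log2 fold, both as deposited from [PSI+] to [psi-], with p-values adjusted by the authors with the Benjamini-Hochberg method and only genes under 0.1. Its base means were checked against the deposited counts: with all 4 [PSI+] columns as separate replicates they differed by at most 0.022% over 1790 of its 1791 genes.

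For the YNB experiment, the submitters' processing notes name cutadapt 1.2.1, Bowtie2 (version not given in the sources used here), HTSeq 0.5.3p3, DESeq 1.6.1 and the build sacCer3. The authors' deposited table gives, for 6190 features, a mean normalized count per condition, a log10 fold and a DESeq p-value with its adjusted value. Per the file headers these are condition means. Counts per library of this experiment were not analysed here, so the count test, camera and the leave-one-out fits planned for it could not be run. In their place stand the authors' adjusted p values for single genes. For gene lists, the median log2 ratio of the means (0.5 added to each) stands with its percentile among 10000 random lists matched on mean level, over genes with a mean of 10 or more.

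Each of the 8 columns of the count table belongs to a sample, and 0 columns were without one. The 4 [PSI+] footprint columns are, per the deposited description, 2 biological and 2 technical replicates. Which columns are runs of 1 library was judged from counting noise over genes with 20 or more reads: 2 pairs agree within sampling noise (chi-square per degree of freedom 1.01, p = 0.262, and 1.0, p = 0.546), and all other pairings of these columns gave 19.35 or more. Each such pair was summed and counted as 1 replicate, and the replicate number is only a name. Each [PSI+] footprint library therefore carries 2 added counts per gene in the fits, and each [psi-] footprint library 1. The [psi-] columns are 2 biological replicates per the deposited description. Over 5076 genes their chi-square per degree of freedom was 1.27 (chi-square test, p = 9.4e-36), slightly more than counting noise. They were kept as n = 2, with their sum as an alternative.

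Gene names came from NCBI RefSeq for assembly R64, which matched 5908 of the 6608 and 5677 of the 6190 feature names; others keep the deposited name. No coordinates are given for the YPD data, which were mapped to another build. Library totals were 2497170 and 3257673 reads ([PSI+] footprints), 3461402 and 3579039 ([psi-] footprints), 5494957 ([PSI+] mRNA) and 2480012 ([psi-] mRNA). A count of 0 allows up to 3 reads, or 0.55 to 1.21 CPM in these libraries.

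Footprint counts were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest over the 4 footprint libraries, and Benjamini-Hochberg adjusted p under 0.05. Translational efficiency was the interaction of library kind and strain in 1 edgeR model over all 6 YPD libraries. CPM are TMM-scaled means with SD. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation camera takes its degrees of freedom from the libraries, which were few, rather than from the genes. Its p values are larger for that reason too. There were 34 lists of translation, stress, metabolic, cell wall, mating and other genes, of which 32 had 5 or more tested members; the mitochondrial genome list matched 0 features and the list of genes specific to the alpha mating type had 1 tested member. mRNA ratios used CPM from library totals with a pseudocount of 0.5 CPM over genes with 10 or more reads in both libraries together, without a test. Ratios of reads carry exact 95% binomial intervals. A fold against 0 reads uses a floor of 3 counts over the group.

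Genes were named by a rule. For footprints these were the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean count of 50 or more and non-overlapping replicates. For efficiency they were the 5 largest each way with a mean footprint count of 50 or more and at least 50 reads in each mRNA library, and for mRNA the 5 largest ratios each way among genes with 100 or more reads. For the SUP35-Cter table the mean normalized count took the place of the raw count and the condition of non-overlap could not be applied; because noncoding RNAs filled its 10 largest rises, the 10 largest protein-coding rises were named as well, a choice made after seeing the data. From each list up to 4 members with the smallest p were named, and SUP35, SUP45, ADE1, URA3, HSP104 and the readthrough list always. The design, the named-gene rule, the lists and most alternatives were fixed before the data were examined.

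The tests were tested on simulated data with 200 changed genes, drawn from the real dispersions, library sizes and each gene's mean level over all libraries compared. Apart from the changes put in, each gene had the same level and dispersion in all simulated libraries. The figures for footprints and efficiency therefore do not cover the unequal spread of the [psi-] and [PSI+] pairs. Nor do they cover mRNA that varies unlike footprints, or genes whose level differs between mRNA and footprints. In the footprint comparison (5135 genes) 82% of 2-fold and 100% of 4-fold changes were recovered with 19 false calls. In the efficiency comparison (5437 genes) 11% of 2-fold and 76% of 4-fold changes were recovered with 4 false calls. In the mRNA comparison (5346 genes) 4.5% of 200 random lists fell outside the central 95%, and 95% of 20 lists shifted by log2 1 were found above it. These lists held randomly drawn genes, so the 4.5% does not cover lists whose members move together.

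The alternatives were RLE and upper-quartile factors, other count filters, DESeq2 1.42.0, limma-voom, leaving out each footprint replicate or the ribosomal protein genes, an estimated correlation, fry, other read minimums and pseudocounts, and other definitions of the gene sets. Added after seeing the data were the counts with 1 subtracted, the [psi-] libraries summed, each run as a replicate, protein-coding genes only, TMM-scaled mRNA totals, a mean of 10 or more footprint reads per gene for efficiency, random lists matched on coding length (10 bins) and mean level (5 bins within each), and other thresholds for the SUP35-Cter table. No group had 3 or more samples. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.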

Results

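Ribosome footprints and mRNA were sequenced from budding yeast of the 74D694 background, either carrying the prion [PSI+] or free of it ([psi-]). [PSI+] is the self-propagating aggregated state of Sup35, the translation termination factor eRF3. A footprint is the stretch of mRNA that a translating ribosome shields from nuclease, so the footprint count of a gene follows how many ribosomes sat on it. In rich medium (YPD), 2 footprint libraries and 1 mRNA library were made per strain. In synthetic medium without uracil (YNB), 2 footprint libraries were made from [PSI+] cells and 2 from [PSI+] cells that overexpressed SUP35-Cter, the C-terminal part of Sup35, which carries the termination activity and lacks the prion-forming domain. The 10 samples thus form 6 groups. In YPD the [PSI+] footprint libraries held 2497170 and 3257673 reads assigned to genes, and the [psi-] ones 3461402 and 3579039. The mRNA libraries held 5494957 reads for [PSI+] and 2480012 for [psi-]. For the YNB experiment the deposited table gives a mean per condition and no total per library, so its depth per sample is unknown here.

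The first comparison asked which genes carried more or fewer ribosomes in [PSI+] than in [psi-] cells. Of 5135 genes tested, 806 rose and 973 fell in [PSI+]. The falls were larger: 533 genes fell and 278 rose by more than 2-fold, and 85 fell and 0 rose by more than 8-fold. SUP35 itself (YDR172W) carried 301 ± 6.97 CPM (footprint counts scaled to the library total with TMM factors) in [PSI+] and 639 ± 7.77 in [psi-] (mean ± SD, n = 2 each), a log2 fold change of -1.09 ± 0.12 (SE). HSP104, the disaggregase on which [PSI+] propagation depends, fell from 1996 ± 18.4 to 485 ± 41.5 CPM, a log2 fold change of -2.04 ± 0.14. SUP45, which encodes the partner termination factor eRF1, stood at 406 ± 48.4 against 344 ± 0.98. ADE1, the adenine synthesis gene whose nonsense allele serves as the usual [PSI+] reporter in this background, stood at 799 ± 192 against 969 ± 27.4. URA3 stood at 55.7 ± 20.5 against 82.7 ± 0.344. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.0029 for SUP35, 6.6e-04 for HSP104, 0.22 for SUP45, 0.30 for ADE1 and 0.12 for URA3.

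The SUP35 call rested on both [psi-] libraries. Without either of them, or with both summed to 1, its adjusted p was 0.052 to 0.054, while its log2 fold change stayed between -1.26 and -0.94 over all 14 alternative settings (adjusted p 2.4e-84 to 0.054). The count of changed genes depended on the same spread. It was 508 or 492 without a [psi-] replicate, 533 with the [psi-] pair summed, and 3384 or 3086 without a [PSI+] replicate. The rises depended on it most: 113 or 110 were left without a [psi-] replicate and 121 with the pair summed, against 395, 382 and 412 falls. The split between rises and falls also moved with the scaling. Of the calls, 45.3% were higher in [PSI+] with TMM, 44.3% with RLE factors and 60.5% with upper-quartile factors, which moved the median of all genes by 0.15 on the log2 scale. DESeq2, which changes scaling, test and filter together, gave 23.3%.

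**Figure D1:**
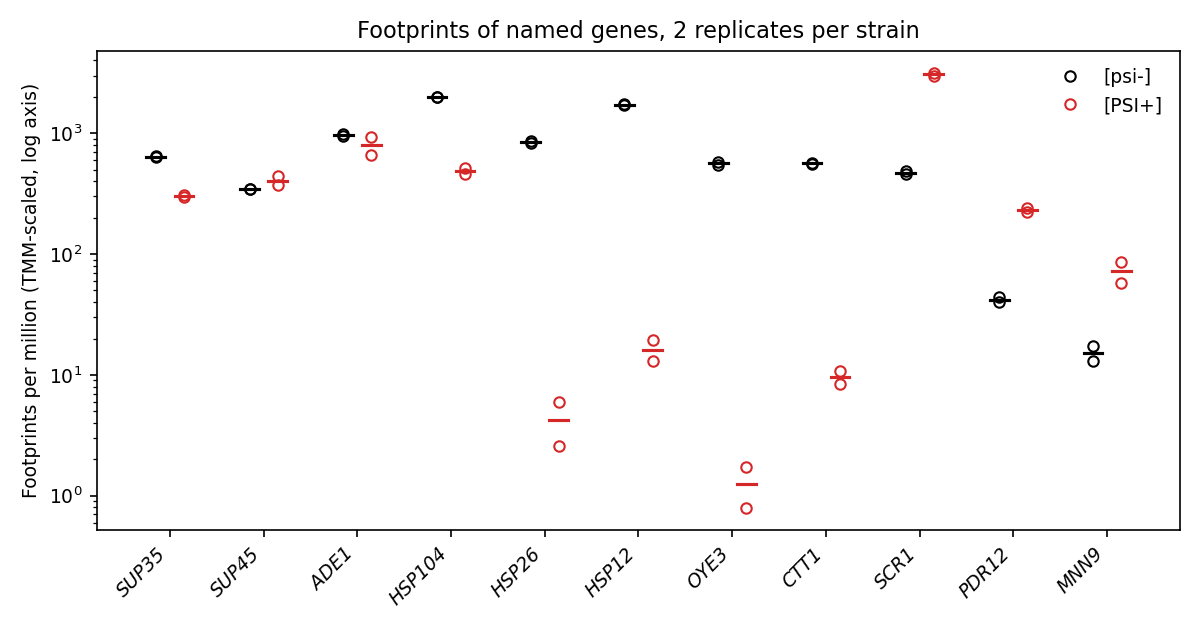
Footprint CPM (TMM-scaled, log axis) of 11 named genes in [psi-] (black) and [PSI+] (red) cells in YPD, with 1 circle per replicate and a bar at the mean of 2. HSP26, HSP12, OYE3 and CTT1 lie far below their [psi-] level in both [PSI+] replicates, whereas SCR1, PDR12 and MNN9 lie above it.

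Among the largest falls of genes with a mean count of 50 or more were genes that yeast turns on under stress. OYE3, an NADPH oxidoreductase gene, had 4 footprint reads over both [PSI+] libraries and 3831 over both [psi-] libraries, 841-fold lower after depth (95% counting interval 328 to 3087). YMR090W had 3 against 2290 reads (670-fold lower, 229 to 3252), OSI1 2 against 1728 (758-fold lower, 210 to 6267) and AAD4 3 against 1111 (325-fold lower, 111 to 1579). ALD3, a cytosolic aldehyde dehydrogenase gene, had 0 reads against 733, at least 214-fold lower with a floor of 3 counts over the group. HSP26, a small heat shock protein gene, had 20 against 5770 reads (253-fold lower, 164 to 415) and HSP12 96 against 11725 (107-fold, 87.7 to 132). SOL4 had 4 against 1242 reads (273-fold, 106 to 1002), FMP16 19 against 2859 (132-fold, 84.4 to 220) and the phosphoglucomutase gene PGM2 12 against 1819 (133-fold, 76.0 to 258). The fits keep the 1 added to every deposited count, which sums to 2 in each [PSI+] library and makes such falls smaller. The log2 fold change was -8.68 for OYE3 and -7.05 for SOL4, and -9.63 and -7.99 with 1 subtracted. Without [PSI+] replicate 1 it went from -7.69 to -8.33 for HSP26, from -7.07 to -8.06 for AAD4, from -7.05 to -7.66 for SOL4, from -6.74 to -7.48 for FMP16 and from -6.61 to -7.50 for PGM2. Without [PSI+] replicate 2 it was -9.38 for OYE3, -6.32 for AAD4, -6.12 for FMP16 and -5.91 for PGM2. Such intervals and floors cover counting error only. AAD4 belongs to a family of closely related aryl-alcohol dehydrogenase genes, so its share of the reads is uncertain.

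The largest rises under the same minimum were smaller. R0040C and R0020C, 2 genes of the 2-micron plasmid, rose by a log2 fold change of 2.75 ± 0.16 and 1.96 ± 0.16. SCR1, the RNA of the signal recognition particle that carries ribosomes to the endoplasmic reticulum, rose from 472 ± 19.4 to 3076 ± 146 CPM in the footprint libraries. It is not translated. The noncoding RNAs SCR1, RPR1, NME1 and TLC1 together made up 1.12% and 1.34% of the footprint reads in the [PSI+] libraries against 0.41% in each [psi-] library. PDR12, the plasma membrane exporter of weak organic acids, rose from 41.9 ± 2.86 to 232 ± 13.5 CPM. ARG7 (arginine synthesis), MRPL3 (mitochondrial ribosome), MNN9 (Golgi mannosyltransferase), ATP25 and MMP1 (S-methylmethionine permease) rose by log2 2.48, 2.42, 2.23, 2.11 and 2.03, and YHR180W-A by 2.35. These 20 largest changes were chosen among genes that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so passing was a condition of the choice. Their calls stayed with the [psi-] pair summed. Only the MMP1 call was lost when a replicate was left out, without [psi-] replicate 2 (log2 1.57, adjusted p 0.074; 1.4e-17 to 0.074 over its alternatives); without [psi-] replicate 1 it stood at 2.65.

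Genes of the general stress response driven by Msn2 and Msn4 were lower in [PSI+] as a group. Of 49 measured members, 42 fell, 0 rose and the rest did not pass, with a median log2 fold change of -2.66 that did not move with ALD3 at its bound. CTT1 (cytosolic catalase), GAD1 (glutamate decarboxylase) and TSL1 (trehalose synthesis) had log2 fold changes of -5.89, -5.83 and -5.69. Of 34 oxidative stress genes 25 fell and 0 rose (median -1.71), among them AAD6 (-5.98) and the methylglyoxal reductase gene GRE2 (-4.32). Of 34 chaperone and heat shock genes 20 fell and 2 rose (median -0.68), with falls of HSP31 (-5.21), SSA3 (-5.48) and SSA4 (-4.76). Adjusted over the list alone, 45, 26 and 23 members changed. Camera, a set test against all other genes, gave adjusted p values of 3.0e-63, 2.6e-25 and 1.7e-09 for the 3 lists, and an adjusted p = 0.21 for each with an estimated correlation between members.

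Proteasome and autophagy genes were also lower, by less. Of 32 proteasome genes 16 fell and 0 rose (median -0.48), including the core particle genes PUP2 (-1.18) and PRE5 (-1.29) and RPN4 (-0.97), the transcription factor of the proteasome genes. Of 35 autophagy genes 12 fell and 1 rose (median -0.49). ATG8, whose product coats the autophagosome membrane, fell by 3.42 on the log2 scale, ATG19 fell by 2.95, and ATG27 rose by 1.21. Adjusted over the list alone, 21 and 13 members changed. Camera gave adjusted p values of 0.014 and 0.022, and an adjusted p = 0.33 for both with an estimated correlation. The autophagy call was lost without [PSI+] replicate 1 (median -0.41) or replicate 2 (median -0.50), and the RPN4 call without either [psi-] replicate (log2 -0.97 and -0.98).

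Cell wall genes were higher in [PSI+]. Of 39 members 20 rose and 3 fell (median 0.66), with rises of GAS1 (1.57 ± 0.12), a glucan-remodelling enzyme gene, and of the glucanase family genes SCW4 (1.26) and SCW11 (1.69). SLT2, the MAP kinase of the cell integrity pathway, fell by 2.89 on the log2 scale. Of 25 ergosterol synthesis genes 12 rose and 2 fell (median 0.56), with ERG5 at 1.54, ERG12 at 0.85 and ERG8 at -0.72. Of 67 amino acid synthesis genes 24 rose and 7 fell (median 0.27), with rises of the lysine gene LYS4 (1.56) and the branched-chain genes ILV1 (1.93), BAT1 (1.61) and ILV2 (1.25). Adjusted over the list alone, 24, 14 and 34 members changed. The camera adjusted p was 1.8e-04, 0.022 and 0.011 for the 3 lists in that order, and 0.30, 0.33 and 0.33 with an estimated correlation. The ergosterol call was lost without [PSI+] replicate 1 (median 0.38). The calls of ERG12 and ERG8 were lost without either [psi-] replicate, and that of ILV2 without [psi-] replicate 1 (log2 1.15).

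Of 75 ribosome biogenesis genes 30 rose and 3 fell (median 0.36), with ENP2 at 0.97, NOP7 at 1.09, UTP20 at 0.90 and DBP8 at 0.87. Of 66 mitochondrial ribosomal protein genes 20 rose and 8 fell (median 0.37), with RSM18 (1.40) and MRPS28 (1.28) up and MRPL7 (-1.52) down. The 138 cytosolic ribosomal protein genes showed no common direction: 14 rose, 16 fell, and the median was -0.18. Many of them are near-identical pairs whose reads could have been divided between copies, so single members are uncertain. Adjusted over the list alone, 34, 35 and 27 members changed. The camera adjusted p was 0.0028, 0.011 and 0.94 for the 3 lists, and 0.33, 0.33 and 0.99 with an estimated correlation. The mitochondrial call was lost without [PSI+] replicate 1 (median 0.31), and the calls of the 4 ribosome biogenesis genes named here without either [psi-] replicate.

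Genes known or proposed to be read through at their stop codon were set beside these. Of 7 measured members 1 passed: BSC5 fell (log2 -2.40, adjusted p = 0.0098 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a call lost without [psi-] replicate 2, and -3.15 with 1 subtracted from every count. BSC1 stood at 1.65 (adjusted p = 0.054 by edgeR's quasi-likelihood test), TLD1 (also BSC2) at 0.77, BSC6 at 0.31, PDE2 at -0.16, IMP3 at -0.02 and OAZ1, the antizyme gene with a programmed frameshift, at -0.52. BSC5 had 5 reads over both [PSI+] libraries and BSC1 10 over both [psi-] libraries. Adjusted over the list alone, 1 member changed. Counts per gene do not show where a footprint lies, so readthrough past a stop codon was not measured.

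In all, 10 of the 32 lists tested passed camera in footprints, 5 up and 5 down. With an estimated correlation 0 passed (edgeR fit, smallest adjusted p = 0.21), against 4 at an unadjusted p under 0.05. Fry, which asks whether the members of a list move one way on balance, called 24, including these 10 in the same direction.

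The replicates were named biological in the deposited description, but the p values measure only the spread between these libraries. The [psi-] pair differed by little more than counting noise (chi-square per degree of freedom 1.27, p = 9.41e-36), the [PSI+] pair by far more (19.35 to 19.83 between their runs). The authors' deposited table for this comparison lists 1791 genes, 470 of them higher and 1321 lower in [PSI+]. Of the 1779 genes called here, 1320 are among the 1502 with an adjusted p under 0.05 in the authors' deposited table, and all 1320 have the same direction there. Both analyses used the same counts, so the shared direction is no independent support.

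The mRNA comparison asked how far the same genes differed in transcript level. It had 1 library per strain, so there was no replicate check and no test. Values are log2 ratios of CPM relative to the median of all 5346 genes, which lay at -0.41. Of 138 cytosolic ribosomal protein genes 135 lay above the all-gene median (list median 2.13), as did 74 of 75 ribosome biogenesis genes (1.95) and 57 of 65 mitochondrial ribosomal protein genes (1.03). Elongation factors (-0.25, percentile 15.8) and termination and surveillance genes (0.22, percentile 65.2) lay inside their random lists. All 51 measured Msn2 and Msn4 targets lay below it (list median -2.88), as did 33 of 34 oxidative stress genes (-2.58) and 24 of 34 chaperone genes (-0.78). Genes of the TCA and glyoxylate cycles (-1.50), sulfur assimilation (-1.25) and autophagy (-1.09) were lower too.

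Among genes with 100 or more mRNA reads the extremes were these. AAD4 had 39 mRNA reads in [PSI+] and 9568 in [psi-], 544-fold lower (95% counting interval 397 to 765). OYE3 was 500-fold lower (36 against 8120 reads), OSI1 404-fold (27 against 4920) and AAD6 264-fold (27 against 3216). YLR108C had 1 read against 492, a 1090-fold lower value whose interval reached from 195 to 43144. At the other end stood the 4 genes of the 2-micron plasmid, which had no read in the [psi-] mRNA library. R0020C with 4869 reads was at least 733-fold higher in [PSI+], R0040C at least 163-fold, R0030W at least 64.8-fold and R0010W at least 35.5-fold. YOR072W-B had 225 against 2 reads (ratio 50.8, interval 13.9 to 422).

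SUP35 mRNA was not lower in [PSI+]: 2709 against 962 reads gave a ratio of 1.27 (interval 1.18 to 1.37), or 0.76 on the log2 scale relative to all genes. HSP104 mRNA was 8.20-fold lower. The ratio was 0.874 for SUP45, 0.954 for ADE1 and 4.51 for URA3 (390 against 39 reads), or 0.22, 0.34 and 2.55 on the log2 scale relative to all genes. Of the 32 lists, 13 lay outside the central 95% of 10000 random lists matched on mean expression, 6 above and 7 below. Besides the lists above, these were the initiation factors (1.00), pyrimidine synthesis (1.51), the readthrough list (1.10, percentile 97.53) and nitrogen catabolite genes (-0.72); the last 2 moved inside with a minimum of 100 reads. Cell wall genes lay at -0.28 (percentile 9.95). The random lists held unrelated genes, so lists whose members move together can lie outside by chance more often.

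Genes that rose in footprints had a median mRNA ratio of 0.37, and 496 of 797 measured (62.2%, exact binomial 95% interval 58.8 to 65.6) lay above the all-gene median. Genes that fell had a median of -0.73, with 673 of 959 (70.2%, 67.2 to 73.1) below it. Both medians lay outside their random lists. Across 5052 genes, which are not independent replicates, footprint and mRNA log2 changes correlated with r = 0.448.

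**Figure D2:**
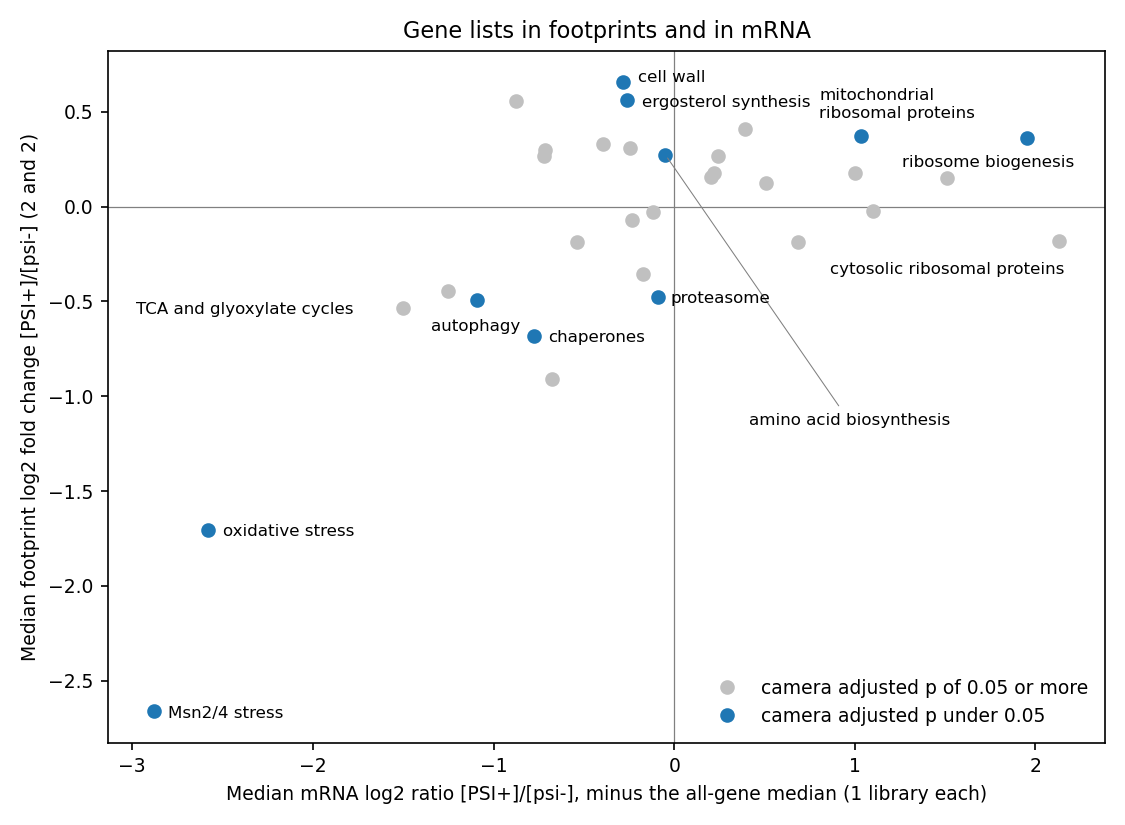
Median log2 fold change in footprints (vertical axis, 2 libraries per strain) against median mRNA log2 ratio relative to all genes (horizontal axis, 1 library per strain), [PSI+] over [psi-], with 1 point per gene list. Blue points passed camera in footprints at the preset correlation; the Msn2/4 and oxidative stress lists lie low on both axes, and the cytosolic ribosomal protein list lies at 2.13 in mRNA and -0.18 in footprints.

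Translational efficiency, the footprint level relative to mRNA, was compared next, as the interaction of library kind and strain. With 1 mRNA library per strain, the spread came from the footprint libraries alone and each mRNA library was assumed to vary like them, so variation of mRNA between cultures was not measured and the calls hold only under that assumption. On it, 974 of 5437 genes rose and 1113 fell in [PSI+]. Cytosolic ribosomal protein genes fell most as a group, from their mRNA values (2.13 against -0.18 in footprints): 98 of 138 fell and 0 rose (median log2 -2.35), among them RPL29 (-4.49 ± 0.23), RPL28 (-4.31) and RPL30 (-3.55). RPL23B had the largest fall (-4.84 ± 0.51) of genes with a mean of 50 or more footprint counts and 50 or more counts in each mRNA library, but has a near-identical copy. Ribosome biogenesis genes followed, with 61 of 75 down and 0 up (median -1.73), including FAF1 (-3.93) and UTP23 (-3.84), while RRS1 fell by 4.71 on the log2 scale. ATX1, a copper chaperone gene, fell by 4.28. Of the mitochondrial ribosomal protein genes 25 of 66 fell and 4 rose (median -0.85), of the initiation factor genes 14 of 29 fell and 2 rose (-0.96), of purine synthesis genes 15 of 28 fell and 2 rose (-0.84), and of pyrimidine synthesis genes 8 of 12 fell and 1 rose (-1.31). These 6 lists passed camera at the preset correlation; with an estimated one the adjusted p was 0.40 for the cytosolic ribosomal proteins and 0.34 for each of the others.

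Cell wall genes had the reverse sign, with 18 of 43 up and 1 down (median 1.23), including PST1 (3.76), SED1 (3.36) and HSP150 (2.06). Of 30 TCA and glyoxylate cycle genes 13 rose and 5 fell (0.85), with KGD1 at 2.77 and IDH1 at 2.41. Of 31 sulfur assimilation genes 13 rose and 1 fell (0.90), with MUP1 at 2.39. Of 35 oxidative stress genes 13 rose and 2 fell (1.00), with OYE2 at 2.82 and CTT1 at -2.74. Nitrogen catabolite genes (0.88; 10 of 31 up and 2 down), phosphate genes (0.86; 8 of 15 up and 2 down) and autophagy genes (0.51; 10 of 37 up and 3 down) were also higher. With an estimated correlation camera gave an adjusted p of 0.40 for autophagy, 0.37 for phosphate and 0.34 for each of the other 5 lists. The hexose transporter list passed at the preset correlation (median 1.41, and camera adjusted p = 0.56 with an estimated one), but HXT6, HXT7 and HXT11 had 0 footprint reads in both strains. Their values came from mRNA reads and from the added counts, 2 per [PSI+] and 1 per [psi-] footprint library. With the added counts subtracted the list median was 1.16. Over genes with a mean of 10 or more footprint reads, camera no longer passed the hexose transporters (adjusted p = 0.35), the phosphate genes (0.14) or the initiation factors (0.071).

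Under the same minimums of 50 the largest single rises were ACH1 (3.88 ± 0.32), which encodes a mitochondrial CoA transferase, PDR12 (3.81 ± 0.22), EGT2 (3.55), NDE1 (3.45) and SPO24 (3.42). SUP35 fell (-1.85 ± 0.20), URA3 fell (-3.15 ± 0.49), and SUP45 (0.01), ADE1 (-0.63) and HSP104 (0.57) did not pass. Of the readthrough list, IMP3 (-2.72), PDE2 (-1.27) and OAZ1 (-1.80) fell, though none of them passed in footprints. The single [psi-] mRNA library held 19 reads for IMP3, 317 for PDE2 and 45 for OAZ1. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.0037 for SUP35, 0.0078 for URA3, 0.0057 for IMP3, 0.0094 for PDE2 and 0.027 for OAZ1. The PDE2 call was lost without either [psi-] replicate, and the OAZ1 call without [psi-] replicate 1.

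Adjusted over the list alone, 106 cytosolic ribosomal protein, 65 ribosome biogenesis and 19 cell wall genes changed in efficiency. The camera adjusted p was 5.9e-24, 1.4e-18 and 4.0e-05 for these lists, and 0.40, 0.34 and 0.34 with an estimated correlation. In all 14 of 32 lists passed, 8 up and 6 down; 0 passed with an estimated correlation (adjusted p of at least 0.34, 2 at an unadjusted p under 0.05), and fry called 14, 11 of them shared. The ribosomal protein, hexose transporter and autophagy lists did not pass fry. Leaving out [PSI+] replicate 1 ended the hexose transporter and phosphate calls (medians 1.23 and 0.91), leaving out [PSI+] replicate 2 the autophagy call (0.47), and leaving out [psi-] replicate 1 the initiation factor call (-0.89).

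The count of genes changed in efficiency ranged from 985 and 996 without a [psi-] replicate to 3373 and 3269 without a [PSI+] replicate, and was 1016 with the [psi-] pair summed. Calls higher in [PSI+] made up 46.7% with TMM, 52.7% with RLE factors and 61.4% with upper-quartile factors, which moved the median of all genes by 0.11 and 0.27. DESeq2, with another scaling, test and filter, gave 25.5%. The direction of every list that passed was kept under these alternatives.

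The YNB experiment asked which footprint changes follow when SUP35-Cter, the part of Sup35 with termination activity, is overexpressed in [PSI+] cells. How far this restored termination was not measured here. In the authors' deposited table, 74 of 6190 features were higher and 8 lower with SUP35-Cter at an adjusted p under 0.05. The raised gene itself, SUP35, was 3.29-fold higher in the authors' deposited table (mean normalized count 20432 against 6207, adjusted p = 0.0053). URA3 was 5.15-fold higher there (adjusted p = 2.0e-06 in the authors' deposited table). SUP45 (0.734), ADE1 (0.805) and HSP104 (0.762) had ratios under 1 in the authors' deposited table, each with an adjusted p of 1.

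Of the raised features, 26 were small noncoding RNAs in the authors' deposited table: 24 of the 58 small nucleolar RNAs listed under snR names, with SCR1 and the spliceosomal RNA LSR1. The authors' deposited table gives 29.1-fold for snR43, 17.1-fold for snR161, 16.9-fold for snR81 and snR33, and 12.9-fold for SCR1 (adjusted p = 1.6e-08). Next came snR35, snR45, snR83, snR46 and snR13, from 11.7-fold down to 8.70-fold in the authors' deposited table. Of the protein-coding genes, 48 were higher and 7 lower in the authors' deposited table. CSS1 was 6.23-fold higher (adjusted p = 1.6e-10), INO1, the inositol synthesis gene, 5.44-fold, and CHO2, a phosphatidylcholine synthesis gene, 4.17-fold in the authors' deposited table. The inositol transporter gene ITR1 was 3.94-fold, the vacuolar sorting receptor gene PEP1 3.77-fold, TUL1 3.76-fold and CWH43 3.73-fold higher in the authors' deposited table. FLO9 (5.66-fold) and EFT2 (3.40-fold) share reads with near-identical copies, FLO1 and EFT1, so their values in the authors' deposited table are uncertain.

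The falls in the authors' deposited table were smaller. DUR12, the urea amidolyase gene, was 3.62-fold lower, LPX1 3.09-fold, RGI1 2.89-fold, CRS5 2.79-fold, RPL35A 2.45-fold, ACM1 2.10-fold, YSF3 1.91-fold and CDC21 1.86-fold in the authors' deposited table. None of the readthrough list passed in the authors' deposited table, where TLD1 had the highest fold of the list at 1.71 and BSC1 the lowest at 0.497.

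**Figure D3:**
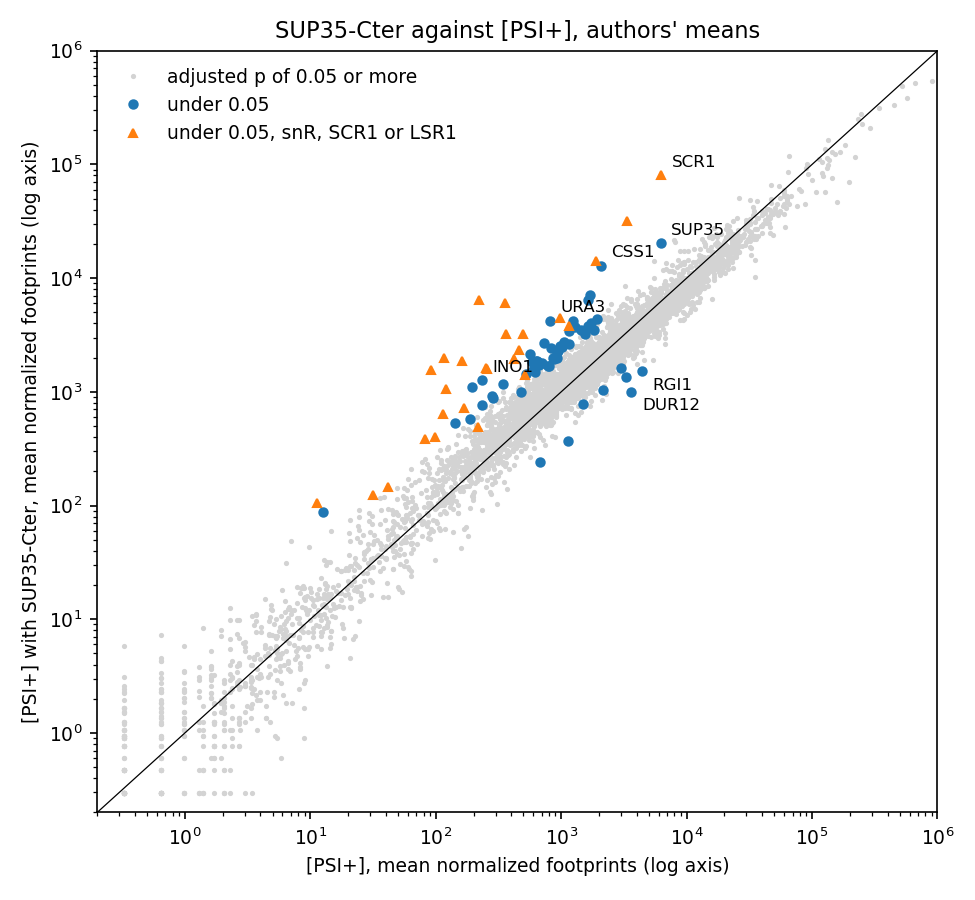
Mean normalized footprints of each feature in [PSI+] cells with SUP35-Cter (vertical log axis) against [PSI+] cells (horizontal log axis) in YNB, as given in the authors' deposited table, with the diagonal marking equality. Of the 82 features under an adjusted p of 0.05, 74 lie above the diagonal, and 26 of those (triangles) are small noncoding RNAs.

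Of 32 gene lists, 5 lay above their random lists in the authors' deposited table: endoplasmic reticulum folding genes (median log2 0.51, with INO1 in the list), sulfur assimilation (0.38, with the sulfate permease SUL2 at 2.93-fold), the iron regulon (0.32), the cell wall (0.31) and pyrimidine synthesis (0.19). Of 47 cell wall genes 6 were called higher and 0 lower in the authors' deposited table, among them FLO9, FLO1, SCW11 (2.45-fold) and EGT2 (2.27-fold). Below their random lists were the proteasome (-0.46), cytosolic ribosomal proteins (-0.19) and mitochondrial ribosomal proteins (-0.18), with 0, 1 and 0 members called lower in the authors' deposited table. These 8 lists lay outside the central 95% of 10000 random lists matched on mean level. The median of all 5566 genes was -0.02. Chance leaves 5% outside only for lists of unrelated genes. Members of a real list can move together, so chance can leave more of them outside. Msn2 and Msn4 targets lay at -0.23 (percentile 3.63), chaperones at -0.33 (percentile 6.48) and oxidative stress genes at -0.08 (percentile 92.8). Only condition means stood behind these values, so they describe these libraries and carry no test between replicates. The random lists for these 32 gene lists were not matched on coding length. Changes with SUP35-Cter rose with coding length (Spearman rho 0.355 over 5408 genes), so length was not separated from these list medians.

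The last comparison set the [PSI+] changes beside those under SUP35-Cter. The 801 measured genes that had risen in [PSI+] had a median log2 fold of 0.11 with SUP35-Cter over [PSI+], above all 10000 random lists matched on mean level, and 60.1% of them were higher. Of them, 18 were called higher and 2 lower in the authors' deposited table. The 972 measured genes that had fallen had a median of -0.16, below all random lists (-0.11 to -0.06), and 30.7% of them were higher. Of these, 3 were called higher and 2 lower in the authors' deposited table. Both sets moved in the same direction with SUP35-Cter as in [PSI+] against [psi-]. Changes with SUP35-Cter rose with coding length (Spearman rho 0.355 over 5408 genes). Against random lists matched on both coding length and mean level, the set that rose still lay above all of them (central 95% -0.03 to 0.03) and the set that fell below all of them (-0.14 to -0.10). With the [psi-] pair summed, the set that rose had a median of 0.35. The YPD and YNB experiments share no library, but differ in medium and in the genome build used for mapping. Across 5125 genes the log2 changes of both comparisons correlated with r = 0.246, genes not being independent replicates.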

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

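Of the tests in this part, those of Sup35 activity in the sets of genes that rose and fell were fixed before their result was seen; the tests on mRNA, on coding length and on the spread of the [psi-] replicates were chosen only after the result was seen.

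All lists, the 20 genes with the largest footprint changes, the 5 genes always named and the readthrough list were searched for footprint and mRNA values of opposite sign relative to all genes, where both the footprint change and the interaction of library kind and strain passed. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment or, for lists, camera, and 5 results met this; genes outside this search, such as RPL29 and MRPL7, can meet it too. With 1 mRNA library per strain this test assumes that mRNA varies like footprints, which was not measured, so it does not establish that both differ. Cell wall genes had a median efficiency change of log2 1.23, from 0.66 in footprints and -0.28 in mRNA (camera adjusted p = 4.0e-05, and adjusted p = 0.34 with an estimated correlation); the mRNA value lay inside its random lists (percentile 9.95), so no change in mRNA was shown. PDR12 had 3.81, from 2.47 in footprints and -1.35 in mRNA (edgeR adjusted p = 0.0030). ARG7 had 2.60, from 2.48 and an mRNA value near all genes, -0.12 (edgeR adjusted p = 0.012). ATP25 had 2.54, from 2.11 and -0.44 (edgeR adjusted p = 0.0057). SUP35 had -1.85, from -1.09 in footprints and 0.76 in mRNA (edgeR adjusted p = 0.0037). In all 15 alternative settings the SUP35 efficiency change kept its call, between -2.14 and -1.59. Its footprint change lost the call in 3 of 14, those without a [psi-] replicate or with that pair summed (edgeR adjusted p between 0.052 and 0.054).

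The widest pattern was the fall of stress genes and the rise of others in [PSI+] footprints. If lost Sup35 activity were its cause, SUP35-Cter should raise the genes that fell and lower those that rose. This holds only if SUP35-Cter restored termination, which was not measured here. The opposite was found. The set that fell lay at percentile 0 of matched random lists (median -0.16) and the set that rose at percentile 100 (median 0.11). Overexpressed SUP35-Cter thus reversed neither set as a whole, in another medium and for condition means. This cannot decide on Sup35 activity, because a shift common to both comparisons, such as the one left open below for secretory genes, was not separated from it. Both sets stayed at these percentiles against lists matched on coding length as well, where the random median for the set that fell moved from -0.09 to -0.12. Too small a spread between the [psi-] replicates stays open. With the [psi-] pair summed, 39 of 42 Msn2 and Msn4 targets called lower kept their call. Over all genes, rises went from 806 to 121 and falls from 973 to 412. This fit takes its spread from the [PSI+] pair alone, and the lone [psi-] sample is assumed to vary like it. The 39 calls thus did not need the small [psi-] spread. The fit cannot show how these genes vary between [psi-] cultures, so it does not decide on this explanation. A difference between the cultures that acts through mRNA levels stays open and may account for part of both sets: their median mRNA ratios were -0.73 and 0.37 relative to all genes, in 1 library per strain, and the prion itself, which could act by other routes, remains an untested alternative.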

How the results depend on the processing

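Leave-one-out, RLE, upper-quartile, filter, DESeq2, voom, ribosomal protein, correlation, fry, threshold and pseudocount alternatives were planned; the summed [psi-] pair, separate runs, protein-coding genes only, 1 subtracted, TMM-scaled mRNA totals, a minimum of footprint reads for efficiency, random lists matched on coding length and other thresholds on the SUP35-Cter table were added after seeing the data. The count of changed footprint genes was 1779 and ranged from 492 to 3384 with 1 replicate left out; it was 533 with the [psi-] pair summed. For efficiency the count was 2087, ranged from 985 to 3373 with 1 replicate left out, and was 1016 with the pair summed. These fits take their spread from 1 strain alone, the lone sample being assumed to vary like the other group, and the [psi-] pair varies far less than the [PSI+] pair. Under every other alternative run, both counts stayed within 1.5 times. The count of lists was 10 in footprints, 0 by camera with an estimated correlation (4 with an unadjusted p under 0.05) and 24 with fry. For efficiency it was 14, 0 by camera with an estimated correlation (2 with an unadjusted p under 0.05) and 14 with fry; it was 11 over genes with a mean of 10 or more footprint reads. Fry asks another question than camera. In footprints the estimated correlation was above the preset 0.01 for Msn2 and Msn4 targets (0.16) and ribosome biogenesis (0.023). It was below 0.01 for oxidative stress (0.0088), chaperones (-0.0018) and the proteasome (-0.030), so a higher correlation between members does not account for the loss of these lists. With an estimated correlation camera also takes its degrees of freedom from the libraries, which were few, rather than from the genes. This alone raises its p values. For oxidative stress the unadjusted camera p went from 1.6e-26 to 0.0083 with an estimated correlation. The loss of lists under this setting is therefore no measure of correlation between members.

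No named gene or list that had passed was reversed under the settings run; IMP3 and HXT1 in footprints and SUP45, BSC1 and BSC5 in efficiency, which had not passed, changed sign. However, the majority direction of the counts was. Footprint calls went from 806 rises and 973 falls to 1219 and 795 with upper-quartile factors. Efficiency calls went from 974 and 1113 to 1122 and 1007 with RLE and 1353 and 852 with upper-quartile factors. Of 150 genes named in footprints, 1875 of the alternative values kept their side of the threshold, 167 lost the call and 32 gained one; for the 140 named in efficiency these were 1964, 89 and 24. For the lists that passed, 66 values held and 14 did not in footprints, 88 and 24 in efficiency, and 37 and 2 in mRNA. All 8 for SUP35-Cter held, but their only alternative was a minimum mean of 100. It left the members and medians of several of these lists unchanged, so it was a weak check. Of the mRNA ratios 60 were counted as moving by less than counting error and 5 by more. The 60 include those of the plasmid genes without a [psi-] mRNA read, whose interval has no upper end, so their moves were not compared with it. The counts of SUP35-Cter genes and lists, the mRNA lists and both sets carried over from [PSI+] stayed within 1.5 times or on the same side of their random lists.

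No paired analysis was possible because the [PSI+] footprint columns carry run numbers rather than replicate numbers and the SUP35-Cter table has only condition means. For the same reason RLE and upper-quartile factors, filters, DESeq2, omission of ribosomal proteins, leave-one-out, an estimated correlation and fry were not run for SUP35-Cter.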

Other observations

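The edgeR calls and the camera tests of the fixed lists were planned; the tests on the secretory list, on the genes raised by SUP35-Cter and on the 2-micron plasmid were chosen only after the result was seen.

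Several groups did not pass as lists in footprints but held single genes with large changes. Of 14 pheromone response genes 3 rose and 2 fell (camera adjusted p = 0.34), among them FAR1, the cell cycle arrest factor (log2 1.40 ± 0.11). Of 7 genes specific to a-type cells 3 rose and 0 fell (adjusted p = 0.21), led by the protease gene BAR1 (1.49 ± 0.19). Of 30 sulfur assimilation genes 11 fell and 4 rose (adjusted p = 0.12), with the glutathione synthesis gene GSH1 at -2.26 ± 0.12. Of 27 purine synthesis genes 10 fell and 2 rose (adjusted p = 0.28), with ADE2 at -1.26 ± 0.12, a gene of the pathway scored in the [PSI+] colour assay. Of 10 vitamin genes of the thiamine and pyridoxine list 3 fell and 1 rose (adjusted p = 0.34), with SNO1 at -3.62 ± 0.34 (-4.40 with 1 subtracted from every count) and SNZ1 at -2.17 ± 0.38 (-2.92 without [PSI+] replicate 2). Of 16 meiosis genes 9 fell and 1 rose (adjusted p = 0.14), with SPS19 at -2.17 ± 0.28. Of 34 respiratory chain genes 13 fell and 5 rose (adjusted p = 0.18), with CYC7 at -2.87 ± 0.18, COX5B at -3.07 ± 0.28 and ATP2 at 1.36 ± 0.14. These genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

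The remaining lists had footprint medians between -0.53 (TCA and glyoxylate cycles, camera adjusted p = 0.072) and 0.56 (hexose transporters, adjusted p = 0.34). Endoplasmic reticulum folding genes had 8 rises and 3 falls of 22 (median 0.33, adjusted p = 0.12), with the chaperone gene KAR2 at 1.65 ± 0.13. Of 10 histone genes 0 rose and 0 fell (by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; median 0.12). Elongation factors had 3 rises of 11, initiation factors 6 rises and 2 falls of 29, and termination and surveillance genes 4 rises and 1 fall of 20. The falling member of the last list was SUP35, and RLI1, the ribosome recycling factor, rose (0.76 ± 0.12), a call lost without either [psi-] replicate.

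Many genes raised by SUP35-Cter in the authors' deposited table encode secreted or membrane proteins, and a list of 129 secretory pathway and membrane transport genes was written after this was seen. With the 17 called genes left out, 100 of 110 members were higher with SUP35-Cter (median log2 0.68), and in [PSI+] against [psi-] 26 of 102 rose and 8 fell (camera p = 0.0014, and p = 0.046 with an estimated correlation). Lists matched on coding length reached at most 0.16 in their central 95%, against 0.68, or 0.17 against 0.74 with the called genes that prompted the list. Length alone thus does not give the list's median. However, the list was chosen from these same data and this matching was on length only, so its excess is no independent support for the pattern. Higher mRNA in [PSI+] cannot be told apart with 1 library per strain, although the list's median there was -0.29 (percentile 0.88). Unequal recovery of membrane-bound ribosomes between libraries stays open and may account for the pattern, with the list at 0.48 in [PSI+] (percentile 100) and SCR1 reads higher in both experiments; a change in translation of these genes would give the same values. SCR1 is not specific evidence for it, since RPR1 and TLC1, also untranslated, rose in [PSI+] footprints (log2 1.64 and 2.44) while NME1 fell (-1.92, all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 24 small nucleolar RNAs were called higher with SUP35-Cter in the authors' deposited table.

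The 48 protein-coding genes called higher with SUP35-Cter in the authors' deposited table were looked up in the [PSI+] comparison. Of the 45 tested there 17 rose and 3 fell (median 0.76, camera p = 4.0e-04, and p = 0.051 with an estimated correlation). Over all features measured in both, 18 were higher in both, against 7.19 due if every feature were equally likely to be called. Likewise 3 were lower in [PSI+] and higher with SUP35-Cter, against 8.72. These due numbers were not matched on level or coding length, with which changes under SUP35-Cter rose.

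The 4 genes of the 2-micron plasmid had 6620 reads in the [PSI+] mRNA library and 0 in the [psi-] one. Too few reads is argued against, since 2988 plasmid reads were due there at the [PSI+] share. A [psi-] strain without the plasmid is argued against by 787 and 792 plasmid reads in the [psi-] footprint libraries. Plasmid sequence left out of the mapping or counting of that library cannot be told apart from loss of the plasmid in that culture: 0 other features with as many [PSI+] reads were at 0 in the [psi-] library, which may go with either.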
